A study of Mus musculus with 6 samples.

How the data were processed

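RNA was measured in fully grown germinal vesicle (GV) oocytes, the immature eggs that still hold an intact nucleus, from 3 Control mice and 3 mice in which Rpa1 is deleted in oocytes (OcKO). Per the labels' protocols, about 20 oocytes freed of cumulus cells were pooled per mouse, from animals 4 to 5 weeks old primed with pregnant mare serum gonadotropin. RNA was made into libraries with a kit for single cells or low input, which does not mark the strand of the transcript. Each library is 1 mouse, so the spread between replicates holds that between animals, of the oocytes sampled and of library preparation. This design cannot separate these.

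The authors deposited counts of reads per gene, not normalized, as 1 table of the series and as 1 file per sample. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the mouse build GRCm38 with STAR 2.5.2b and counted with featureCounts of Subread 1.5.2. The annotation release, the strand setting and the treatment of reads that match several places or several genes are not given in the sources used here. The table and the per-sample files held 49315 genes each and differed in 0 values. Of the gene identifiers, 99.5% were found in GENCODE M21 (GRCm38), and 91.4% of those had the same start and end there. Coordinates are those of the deposited files, which list exons by position. In the table of the series, 174 genes had no name and kept their identifier. Of the 51 genes that were called or picked by the rules for naming, 11 share exonic sequence with another gene in the deposited annotation.

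Total counts were 37693672, 41402926 and 36612443 in Control replicates 1 to 3 and 42203260, 44575222 and 36280148 in OcKO replicates 1 to 3. At this depth 1 count is worth 0.0224 to 0.0276 CPM before TMM scaling. Where all 3 Control libraries had 0 counts, the fold is a bound against 3 counts over the group. For 1 to 3 Control counts, the ratio of summed counts scaled to library size is given with its exact 95% counting interval. The medians of the gene lists were the same to 2 decimals with such genes at their bound. Such bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

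Libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, default settings) on the deposited counts, with TMM scaling and the filterByExpr filter, which left 16060 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM (counts-per-million) values are TMM-scaled unless summed over a list. Values are means ± SD over 3 libraries, and log2 fold changes carry a standard error (SE). The SE was derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Positive log2 fold changes are higher in OcKO. The TMM factors were 0.963, 0.917 and 0.949 in Control and 1.04, 1.02 and 1.12 in OcKO. Scaling by library size alone raised the median log2 fold change of all tested genes by 0.17, and DESeq2 size factors by 0.02.

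A set of 29 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 29 lists, and again with an estimated correlation and with fry. The p53 target and apoptosis lists share members, as do the p53 target and ribosomal protein lists. The genes named are Rpa1, Rpa2 and Rpa3, then the 8 with the largest positive and the 8 with the largest negative log2 fold change among called genes. These had to have no overlap of the libraries, a mean of at least 5 CPM in the higher group and a symbol of a named gene. The rule left out symbols made of Gm and digits, ending in Rik or -ps, made of a bare identifier, or beginning with AC, AL, BC or AI and digits. Of the called genes, 22 qualified on the higher side and 1, Rpa1, on the lower side. In each list, up to 3 called members with the smallest p are named, or, where none was called, the 1 member with the smallest p, as values only. Some genes picked by these rules are not reported here.

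Per library, total counts, genes detected, the share of mitochondrially encoded and of the 100 most abundant genes, and the summed CPM of markers of other cell types were compared with exact two-sided permutation tests. With 3 against 3 libraries these cannot give a p under 0.1. A mean log2 CPM difference between the longest 20% and the shortest 20% of genes by genomic span was compared in the same way. The share of called genes within 20 Mb of Rpa1 was compared with the share elsewhere by a two-sided Fisher's exact test.

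No libraries were duplicates: the lowest chi-square per degree of freedom between a pair was 122.7. Pearson's r of log2 CPM, across genes, was 0.843 to 0.906 within groups and 0.800 to 0.896 between groups.

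The scripts were tested on simulated data, 3 sets of 16060 genes drawn for the comparison of OcKO with Control. edgeR called 4.35% of genes changed 2-fold, 39.1% of those changed 4-fold, 57.7% at 8-fold and 60.9% at 16-fold. Of the calls, 3.12% were unchanged genes. In the same sets, 282 of 580 calls of DESeq2 1.42.0 (48.6%) were unchanged genes. Both shares depend on how few genes were changed in the simulation. They therefore do not give the share of false calls in the real comparison. Among simulated lists, camera called the 1 list that was raised and 0 others. Genes were drawn independently of each other there, so this does not test camera where genes are correlated.

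Alternatives were DESeq2, limma voom, DESeq2 size factors, library size alone, no filter or a filter at 5 CPM in 3 libraries, a block on the replicate number and leaving out each replicate. Further ones were stricter thresholds, leaving out mitochondrially encoded and predicted genes, other windows and other length groups. The newer quasi-likelihood form of edgeR and the thinning of libraries to the smallest total were added after seeing the data. Without 1 library the filter was run again and left 16765 to 17597 genes, so the tested members of a list may differ from those of the main test.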

Results

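RNA sequencing compared GV oocytes of 3 Control mice with those of 3 mice lacking Rpa1 in the oocyte (OcKO). Rpa1 encodes the large subunit of replication protein A, which binds single-stranded DNA during replication, recombination and repair. The series asks about the role of RPA1 in repairing DNA damage during oogenesis. The libraries held 36280148 to 44575222 counts each. Transcripts of the oocyte led in both groups: Ldhb made up 1.30% of counts in Control and 1.00% in OcKO, and Gdf9 made up 0.986% and 0.737%. The first principal component held 34.9% of the variance and placed all 3 Control libraries on one side of all 3 OcKO libraries. The second held 23.4% and had Control replicates 1 and 2 at its ends. Control replicates 1 and 3 correlated best with OcKO replicate 2 (Pearson's r of 0.867 and 0.896), and Control replicate 2 with Control replicate 3 (0.858). Each OcKO library correlated best with another OcKO library.

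Rpa1 (ENSMUSG00000000751, chromosome 11, 75298166 to 75348324, minus strand, GRCm38) was nearly lost from the OcKO oocytes. The Control libraries held 156, 155 and 140 CPM (150 ± 8.86, SD, n = 3) and the OcKO libraries 7.76, 4.14 and 6.84 CPM (6.25 ± 1.89, SD, n = 3). Rpa1 was 24.0-fold lower, with a log2 fold change of -4.59 (SE 0.31, edgeR adjusted p = 0.0064). The counts cover the whole gene, so reads from any exons left in the deleted allele are included. The genes of the other RPA subunits were not called. Rpa2 stood at 149 ± 37.1 CPM in Control and 173 ± 11.9 CPM in OcKO (SD, n = 3; log2 fold change 0.21, SE 0.22). Rpa3 stood at 26.8 ± 6.68 and 25.5 ± 8.09 CPM (log2 fold change -0.07, SE 0.36). The Rpa1 adjusted p passed 0.05 without Control replicate 1 (0.0422), OcKO replicate 1 (0.0415) or OcKO replicate 2 (0.0125). It was 0.0526 without Control replicate 2, 0.0588 without Control replicate 3 and 0.0959 without OcKO replicate 3, and the log2 fold changes over the 6 fits lay between -4.78 and -4.33.

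**Figure D1:**
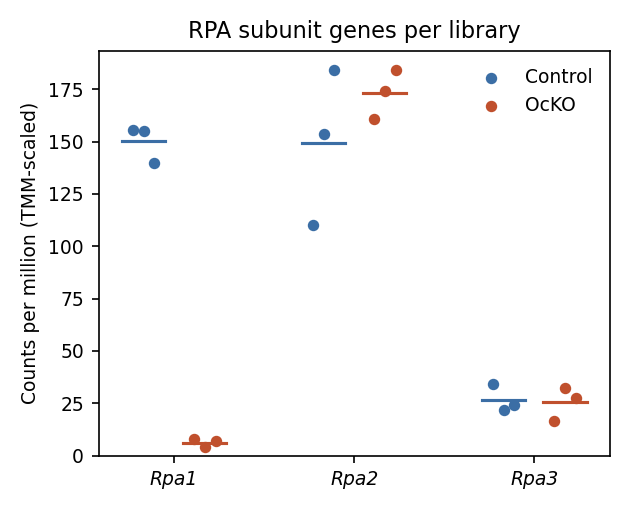
TMM-scaled CPM (counts-per-million) of Rpa1, Rpa2 and Rpa3 in each library, with Control in blue, OcKO in red and bars at the group means. Rpa1 lies between 140 and 156 CPM in Control and between 4.14 and 7.76 CPM in OcKO, while the 2 other subunits overlap between the groups.

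Beyond Rpa1, the calls were genes that rose: 22 of 16060 tested genes were higher in OcKO and 1, Rpa1 itself, was lower. Many of the genes that rose were nearly silent in Control oocytes. Of the 22, 3 had no Control counts, 8 had 1 to 3 counts over the 3 Control libraries and 11 had more. In all 22 the OcKO libraries lay above all Control libraries. Clca2, a gene of the family named for calcium-activated chloride channels, had 0 Control counts and 22.7 ± 3.35 CPM in OcKO (SD, n = 3), at least 820-fold higher (edgeR adjusted p = 0.0282). Hapln3, which encodes a hyaluronan and proteoglycan link protein, had 21.7 ± 10.05 CPM, at least 777-fold higher. Rbp2, which encodes a cellular retinol-binding protein, had 17.5 ± 7.80 CPM, at least 626-fold higher (both adjusted p = 0.0450). Mcam, which encodes a cell adhesion molecule of the immunoglobulin superfamily, had 1 Control count and 72.2 ± 23.5 CPM in OcKO, a ratio of 7814 (interval 1402 to 308673, adjusted p = 0.0049).

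Among the 8 largest rises were also Calhm2, Tmem40, Grhl3 and Eda2r. Calhm2, of the calcium homeostasis modulator family, had 2 Control counts and 50 ± 43.8 CPM in OcKO, a ratio of 2640 (interval 730 to 21801, edgeR adjusted p = 0.0250). OcKO replicate 3 held 100.4 CPM of Calhm2, against 22.3 and 27.2 CPM in the others, and without it the log2 fold change was 10.17 in place of 11.19 (adjusted p = 0.0959). Its exons overlap those of Pdcd11 on the opposite strand, which stood at 31.0 CPM in Control and 31.4 CPM in OcKO. Tmem40, a transmembrane protein gene, had 2 Control counts and 38.5 ± 20.1 CPM, a ratio of 2078 (interval 575 to 17166, adjusted p = 0.0144). Grhl3, which encodes a grainyhead-like transcription factor of epithelia, had 1 Control count and 18.1 ± 8.16 CPM, a ratio of 1988 (interval 356 to 78559, adjusted p = 0.0297). Eda2r, the receptor for ectodysplasin A2, had 1 Control count and 14.8 ± 1.98 CPM, a ratio of 1608 (interval 288 to 63556, adjusted p = 0.0313). The 1 Control count of Mcam, Grhl3 and Eda2r lay in Control replicate 3. Without that library their log2 fold changes were 14.5, 12.5 and 12.2, in place of 12.5, 10.5 and 10.2. Of the 6 fits without 1 library, Mcam kept its call in 4, Tmem40 in 1 and the other genes of the 8 in 0.

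The genes that rose from more than 3 Control counts, other than p53 targets, included Sept9, Ms4a10, Wdr41, Afg1l, Slc23a3, Calb1 and Itga3, and those from 1 to 3 Control counts also included Specc1, Hrh1 and Ggt5. These 10 were chosen to be named after their values were seen. Sept9, which encodes a septin, had a log2 fold change of 7.13 (SE 0.58, edgeR adjusted p = 0.0144). The smallest of the 10 belonged to Calb1, which encodes the calcium-binding protein calbindin (log2 fold change 2.08, SE 0.25, adjusted p = 0.0450). At an unadjusted p under 0.05, 952 genes were higher and 837 lower by edgeR, and 1352 and 449 with library size alone in place of TMM. Libraries did not overlap for 19.4% of tested genes, where chance gives 10%, and 1721 of these genes were higher and 1392 lower in OcKO. The number of calls moved with the libraries and with the test. Without 1 library, edgeR called 3 genes higher and 1 lower (without Control replicate 1), 2 and 0 (Control replicate 2), 0 and 0 (Control replicate 3), 1 and 2 (OcKO replicate 1), 4 and 1 (OcKO replicate 2) and 0 and 0 (OcKO replicate 3). DESeq2 called 770 higher and 393 lower, limma voom called 0 higher and 1 lower, and edgeR called 60 higher and 8 lower at a minimum of 5 CPM.

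**Figure D2:**
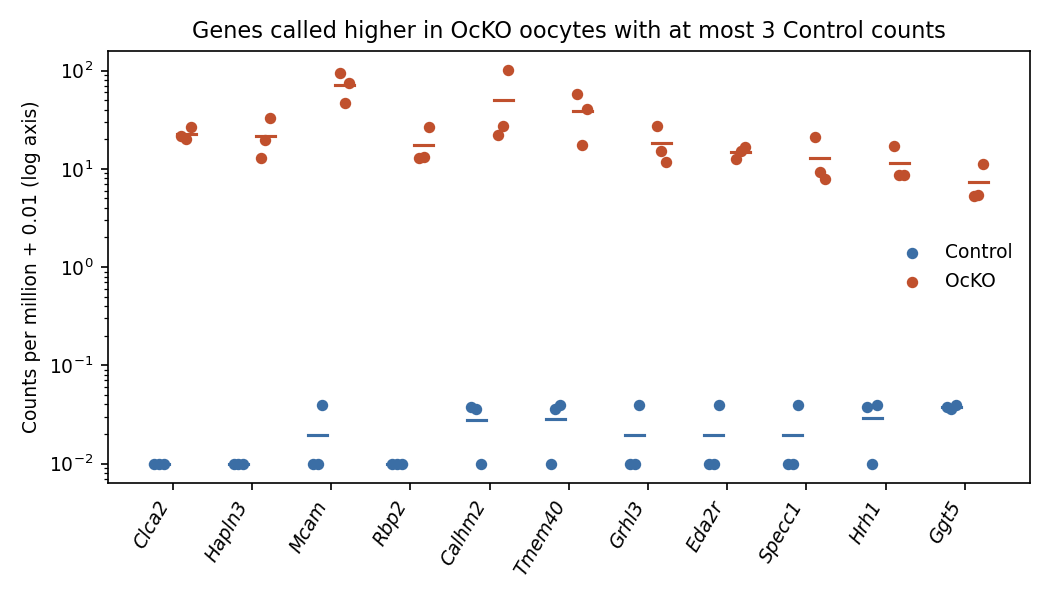
CPM plus 0.01, on a log axis, of the 11 genes called higher in OcKO that had at most 3 counts over the Control libraries, ordered by fitted log2 fold change, with Control in blue, OcKO in red and bars at the group means. In every gene the 3 OcKO libraries lie above the 3 Control libraries, and 3 of the genes have 0 Control counts.

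Target genes of p53, the transcription factor that responds to DNA damage, were higher as a list (camera adjusted p = 5.39e-10; adjusted p = 0.0535 with an estimated correlation). Of 31 tested members, 4 rose (edgeR, adjusted over all genes), 16 were higher when adjusted over the list alone and 27 had a positive log2 fold change. The OcKO libraries lay above all Control libraries for 18 members and below for 1. The called members were Eda2r, Pmaip1, Btg2 and Mdm2, the last named after its values were seen. Pmaip1, which encodes the pro-apoptotic protein NOXA, went from 0.111 ± 0.0732 to 35.7 ± 29.2 CPM (log2 fold change 8.29, SE 0.92, adjusted p = 0.0383). OcKO replicate 3 held 69.2 CPM of Pmaip1, against 15.8 and 22.0 CPM in the others, and without it the log2 fold change was 7.37. Btg2, an antiproliferative gene, went from 28.8 ± 13.0 to 225 ± 49.1 CPM (log2 fold change 2.96, SE 0.36, adjusted p = 0.0450). Mdm2, which encodes the ubiquitin ligase that degrades p53, went from 193 ± 27.4 to 716 ± 178 CPM (log2 fold change 1.89, SE 0.23, adjusted p = 0.0450). In the 6 fits without 1 library none of the 4 kept its call (adjusted p of 0.0612 to 0.2895), and of the 31 members DESeq2 called 14 higher and limma voom 0. The median log2 fold change of the list was 1.2, also 1.2 with genes without Control counts at their bound, 1.21 with DESeq2 size factors and 1.42 with library size alone. Leaving out each library gave camera adjusted p values of 1.05e-09 to 1.77e-06. RNA levels of these genes do not show whether p53 or another transcription factor raised them, and p53 activity was not measured.

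**Figure D3:**
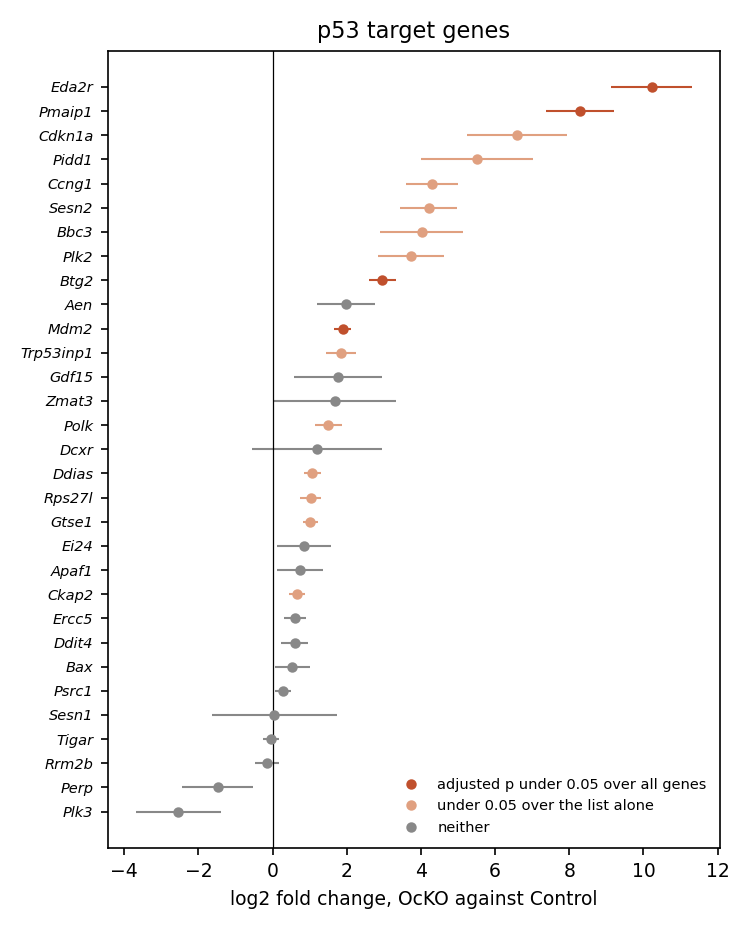
Fitted log2 fold change, OcKO against Control, of each of the 31 tested p53 target genes, with bars of 1 standard error derived from the F statistic. Dark red marks the 4 genes past an adjusted p of 0.05 over all genes, light red those past it over the list alone, grey neither, and 27 of the 31 points lie above 0.

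Apoptosis regulators were higher as a list (camera adjusted p = 0.0217; adjusted p = 0.238 with an estimated correlation), with members on both sides. Of 28 tested, 1 rose over all genes (Pmaip1), and 18 had positive and 10 negative log2 fold changes, with a median of 0.56. Adjusted over the list alone, 2 were higher and 1 lower. Outside the naming rule, the lower one was Bik, a pro-apoptotic BH3-only gene, at 35.9 ± 4.11 CPM in Control and 8.85 ± 5.20 CPM in OcKO. The camera adjusted p of the list was 0.0716 without OcKO replicate 1 and 0.0516 without OcKO replicate 3.

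Transcripts encoded by the mitochondrial genome were higher as a list (camera adjusted p = 4.5e-07; adjusted p = 0.115 with an estimated correlation). All 13 tested genes had positive log2 fold changes (median 1.09), 0 were called by edgeR over all genes and 8 were higher when adjusted over the list alone. At an unadjusted p under 0.05, 8 were higher and 0 lower; DESeq2 called 8 higher and limma voom 0. The 3 OcKO libraries lay above all Control libraries for 11 of the 13. mt-Nd4, which encodes a subunit of respiratory complex I, stood at 104 ± 14.4 CPM in Control and 244 ± 41.8 CPM in OcKO (SD, n = 3; log2 fold change 1.24, SE 0.20, edgeR adjusted p = 0.110). The median was 1.11 with DESeq2 size factors and 1.26 with library size alone. These transcripts were a small share of every library, 0.0727 ± 0.0068% of counts in Control and 0.167 ± 0.0173% in OcKO (SD, n = 3). Counting could split or lose reads shared with nuclear copies of mitochondrial sequence.

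The 75 tested nuclear oxidative phosphorylation genes had a median log2 fold change of 0.11 (camera adjusted p = 0.524). Sdhb, a subunit of succinate dehydrogenase, had the smallest p, at 50.4 ± 4.30 and 99.2 ± 18.6 CPM in Control and OcKO. Cytosolic ribosomal protein genes were higher as a list, by a small amount (camera adjusted p = 0.00468; adjusted p = 0.814 with an estimated correlation and 0.343 with fry). Of 90 tested, 66 had positive log2 fold changes, with a median of 0.28. edgeR called 0 over all genes and 1 higher when adjusted over the list alone, 15 were higher at an unadjusted p under 0.05, and DESeq2 called 7 higher and limma voom 0. The gene past 0.05 over the list alone was Rps3a1, at 32.2 ± 3.96 CPM in Control and 89.6 ± 1.35 CPM in OcKO (log2 fold change 1.48, SE 0.21, edgeR adjusted p = 0.0694); ribosomal protein genes have many processed copies, so their counts are uncertain. The camera adjusted p was 0.0871 without Control replicate 1, 0.0735 without Control replicate 3 and 0.563 without OcKO replicate 3.

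Genes of oocyte growth, maternal mRNA storage and meiotic maturation were lower as lists by camera with the preset correlation only, with no member called over all genes. Of 49 oocyte growth and maternal factors, 38 had negative log2 fold changes (median -0.21; camera adjusted p = 0.00194; adjusted p = 0.382 with an estimated correlation and 0.130 with fry). Bmp15, an oocyte growth factor that acts on follicle cells, stood at 6157 ± 1445 CPM in Control and 3216 ± 847 CPM in OcKO (SD, n = 3; log2 fold change -0.94, SE 0.25, edgeR adjusted p = 0.203). Of 38 genes of maternal mRNA storage and decay, 29 had negative log2 fold changes (median -0.33; camera adjusted p = 0.00181; adjusted p = 0.363 with an estimated correlation and 0.117 with fry), and 1, Cnot3, was lower when adjusted over the list alone. Cnot3, a subunit of the CCR4-NOT deadenylase, stood at 359 ± 33.5 and 164 ± 11.1 CPM (log2 fold change -1.13, SE 0.16, edgeR adjusted p = 0.0763). Of 38 meiotic maturation and cell cycle regulators, 27 had negative log2 fold changes (median -0.26; camera adjusted p = 0.0239; adjusted p = 0.238 with an estimated correlation and 0.0718 with fry). Pde3a, the phosphodiesterase that lowers oocyte cAMP, stood at 299 ± 51.6 and 160 ± 22.1 CPM (edgeR adjusted p = 0.127). At an unadjusted p under 0.05, edgeR found 8, 7 and 5 members of these lists lower and 0 higher, DESeq2 called 2, 4 and 2 lower, and limma voom called 0.

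The meiotic maturation list had a camera adjusted p of 0.0849 with library size alone, 0.0504 with a replicate block, 0.105 without Control replicate 1, 0.0700 without OcKO replicate 2 and 0.104 without OcKO replicate 3. With library size alone, which moved the median of all genes by 0.17, the medians of the growth, storage and maturation lists were -0.04, -0.17 and -0.09. Among other oocyte lists, spindle checkpoint and kinetochore genes had a median of -0.13 (camera adjusted p = 0.182) and DNA methylation and chromatin regulators a median of -0.14 (adjusted p = 0.229). Cenpf, a kinetochore protein gene, stood at 496 ± 20.4 and 309 ± 79.0 CPM, and Dnmt1, the maintenance DNA methyltransferase, at 6188 ± 493 and 3326 ± 558 CPM (edgeR adjusted p = 0.1196). When adjusted over the list alone, 3 of the 42 DNA methylation and chromatin regulators were lower: Dnmt1, Dnmt3a and Ezh2, the last pair named after their values were seen. The DNA methylation list had a camera adjusted p of 0.0445 without OcKO replicate 1.

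**Figure D4:**
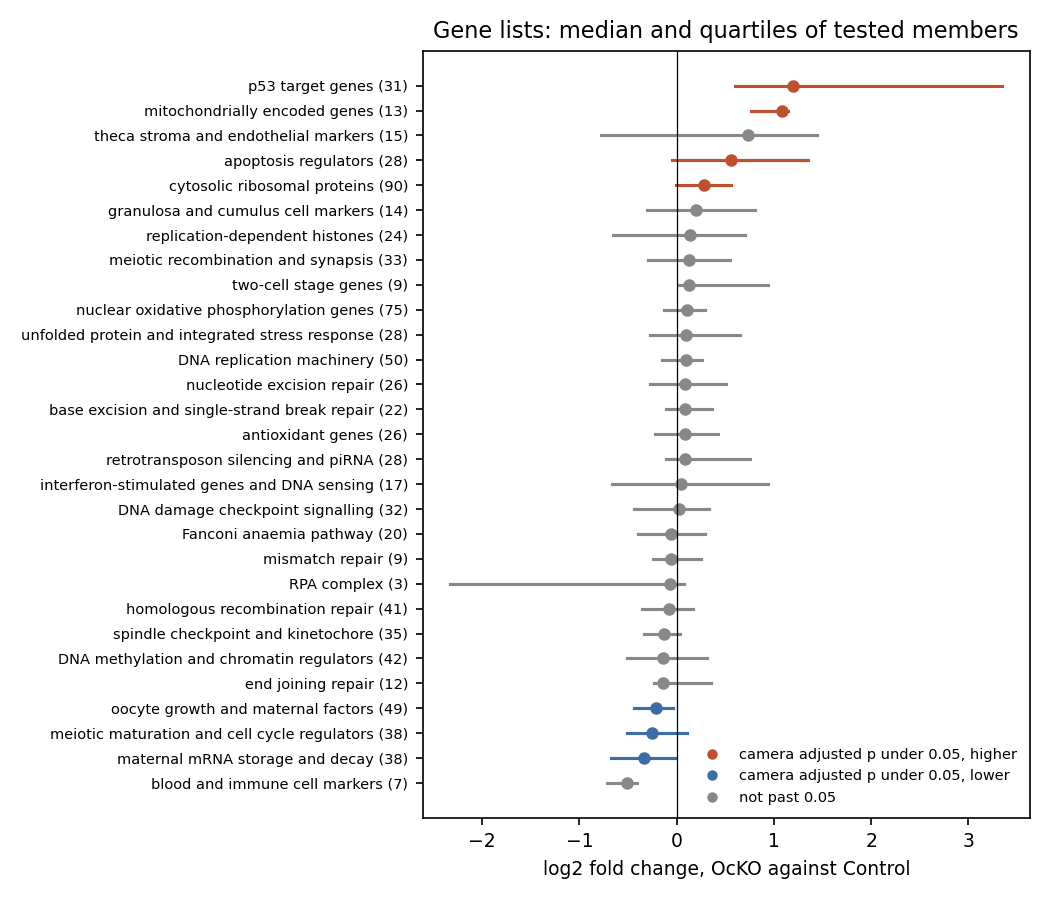
Median log2 fold change, OcKO against Control, of each of the 29 gene lists, with lines from the first to the third quartile of the tested members, whose number is in parentheses. Red and blue mark the 7 lists past a camera adjusted p of 0.05 with the preset correlation, of which 4 are higher and 3 lower; with an estimated correlation none passes, and grey marks the rest.

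No list of DNA repair or replication genes passed the test. Of the 240 genes on 9 such lists, edgeR called 0 over all genes and 0 in any list when adjusted over the list alone. At an unadjusted p under 0.05, 12 were higher and 13 lower, DESeq2 called 9 higher and 7 lower, and limma voom called 0. The median log2 fold changes were 0.02 for DNA damage checkpoint signalling (32 tested; camera adjusted p = 0.524), -0.08 for homologous recombination repair (41; 0.423) and 0.13 for meiotic recombination and synapsis (33; 0.596). They were -0.14 for end joining (12; 0.795), -0.06 for the Fanconi anaemia pathway (20; 0.826), 0.09 for base excision and single-strand break repair (22; 0.866) and 0.09 for nucleotide excision repair (26; 0.984). Mismatch repair had a median of -0.06 (9; 0.795) and the replication machinery 0.09 (50; 0.975), and camera placed the replication machinery on the lower side. The 3 RPA genes had a median of -0.07 (0.182), and fry, which tests whether the members move one way on balance, gave this list an adjusted p of 0.0022. That value rests on Rpa1, the deleted gene, since Rpa2 and Rpa3 changed little (log2 fold changes of 0.21 and -0.07). With library size alone, 7 of the 29 medians took the positive sign in place of the negative: the RPA, homologous recombination, end joining, Fanconi, mismatch repair, spindle checkpoint and DNA methylation lists.

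Members with the smallest p in several of these lists are given as values. Trip13, an ATPase of meiotic recombination, stood at 11.7 ± 4.79 CPM in Control and 44.96 ± 10.9 CPM in OcKO (SD, n = 3; edgeR adjusted p = 0.122). Mus81, a structure-selective endonuclease, stood at 242 ± 14.0 and 140 ± 11.5 CPM (adjusted p = 0.1198). Timeless, of the replication fork protection complex, stood at 206 ± 56.5 and 119 ± 20.1 CPM, and Dclre1c, which encodes the Artemis nuclease, at 21.1 ± 1.49 and 11.4 ± 3.12 CPM. Exons of Dclre1c overlap those of Suv39h2 on the opposite strand. Faap20 stood at 17.7 ± 2.45 and 39.5 ± 11.8 CPM, Neil2 at 14.2 ± 0.795 and 6.24 ± 2.69 CPM, and Cdk7 at 127 ± 20.3 and 231 ± 66.8 CPM. Rfc3, a clamp loader subunit, stood at 60.1 ± 0.889 and 101 ± 18.1 CPM.

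Of the stress and other gene lists, none of the following passed camera. Unfolded protein and integrated stress response genes had a median log2 fold change of 0.10 (28 tested; adjusted p = 0.743), antioxidant genes 0.08 (26; 0.743), interferon-stimulated and DNA sensing genes 0.04 (17; 0.606) and replication-dependent histones 0.14 (24; 0.743). Genes of the 2-cell stage had a median of 0.12 (9; 0.826; 3.64e-05 without OcKO replicate 1) and genes of retrotransposon silencing and piRNA 0.08 (28; 0.430). Without OcKO replicate 1 the filter left 17317 genes in place of 16060, so the 2-cell genes tested there may not be the same 9. edgeR called 0 members of these stress and other lists over all genes. When adjusted over the list alone, 2 stress response genes were higher and 2 lower, 1 histone gene and 1 retrotransposon silencing gene were higher, and 1 gene of the 2-cell stage was higher and 1 lower. Sesn2, a stress-inducible gene that is also on the p53 list, stood at 6.99 ± 5.50 CPM in Control and 129 ± 70.9 CPM in OcKO (SD, n = 3; edgeR adjusted p = 0.1196). Tex19.2, a germ cell gene with a close copy in Tex19.1, stood at 15.1 ± 2.85 and 85.8 ± 31.0 CPM (adjusted p = 0.0675), and Zfp809, which encodes a zinc finger protein that silences retroviruses, at 10.03 ± 1.44 and 39.5 ± 4.39 CPM (adjusted p = 0.0831). Txnrd1 stood at 210 ± 25.9 and 123.05 ± 21.5 CPM, Mx1 at 0.105 ± 0.159 and 2.64 ± 1.12 CPM, and Hist1h1e had 0 Control counts and 0.587 ± 0.0711 CPM.

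edgeR called 0 markers of other ovarian or blood cells over all genes; when adjusted over the list alone, 1 granulosa marker was higher, and 2 theca, stroma or endothelial markers were higher and 1 lower. At an unadjusted p under 0.05 these numbers were 1, 3 and 1, and DESeq2 called 1, 1 and 1. The summed CPM of granulosa and cumulus markers was 448 ± 90.9 in Control and 422 ± 53.8 in OcKO (exact permutation p = 0.7, n = 3 per group), of which Bmpr1b and Esr2 gave most. The sums were 327 ± 27.5 and 307 ± 60.9 for theca, stroma and endothelium (p = 0.8, exact permutation test) and 39.6 ± 5.56 and 46.3 ± 7.66 for blood and immune cells (p = 0.2, exact permutation test). The median log2 fold changes of the tested members were 0.20 (14; camera adjusted p = 0.322), 0.74 (15; 0.0862) and -0.51 (7; 0.215). The theca, stroma and endothelial list had a camera adjusted p of 0.0150 without Control replicate 3, where the filter was run again and the tested members may differ. Nr5a1, a steroidogenic transcription factor, had 0 Control counts and 1.90 ± 0.985 CPM in OcKO, Cyp17a1, a theca enzyme, 0 counts and 0.619 ± 0.154 CPM, and the T cell gene Cd3e stood at 0.487 ± 0.0879 and 0.293 ± 0.135 CPM (edgeR adjusted p = 0.827).

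More genes were detected in OcKO oocytes. The libraries held 21186 ± 1240 genes with 1 or more counts in OcKO and 18705 ± 562 in Control (SD, n = 3, exact permutation p = 0.1, the smallest this design allows). After thinning every library to the smallest total, an addition made after seeing the data, the numbers were 21017 ± 1238 and 18617 ± 644. The 100 most abundant genes held 21.3 ± 0.479% of counts in OcKO and 23.9 ± 2.29% in Control (exact permutation p = 0.1). Mean total counts in OcKO were 1.06 times those in Control (exact permutation p = 0.5). Over the 9 measures of this family, the smallest Benjamini-Hochberg adjusted p was 0.225, that of the genes detected, of the mitochondrial share and of the 100 most abundant genes.

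Genes of long genomic span were examined because DNA damage can block transcription along a gene. The mean log2 CPM of the longest 20% of tested genes lay above that of the shortest 20% by 2.48 ± 0.0818 in Control and 2.28 ± 0.199 in OcKO, a difference of -0.20 (exact two-sided permutation p = 0.3, n = 3 per group). The difference was -0.088 without OcKO replicate 3 and -0.385 for genes with a name other than Gm or Rik (exact permutation p = 0.1). Across genes, which are not independent replicates, Spearman's rho of log2 fold change with span was -0.12. Within 20 Mb of Rpa1, 2 of 480 tested genes were called (0.417%), against 20 of 15579 elsewhere (0.128%; Fisher's exact p = 0.139), and within 10 Mb it was 0 of 281 (p = 1). The 2 genes were Itga3 and Specc1, named after their values were seen.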

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

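edgeR's newer quasi-likelihood form and thinning to the smallest total were chosen after seeing the data. Against 22 genes higher and 1 lower, edgeR called 23 and 1 with DESeq2 size factors, 29 and 1 with library size alone, 33 and 1 without a filter (27431 genes tested against 16060), and 22 and 1 from the per-sample files. A minimum of 5 CPM in 3 libraries gave 60 and 8 with 10094 genes tested, and leaving out mitochondrially encoded and predicted genes 36 and 2 with 13048 tested. All 22 higher genes were called again in these settings and by DESeq2, which called 770 and 393; 66.2% of its calls were higher, against 95.7% for edgeR. The newer edgeR form called 22 and 1, with 9 of the 22 shared. Of the 11 called higher genes picked for naming or named as p53 targets, it kept 3, Mcam, Btg2 and Mdm2. limma voom called 0 and 1 (1212 and 992 at an unadjusted p under 0.05). An adjusted p under 0.01 left 1 higher gene and 1 lower, and a fold of at least 2 left 22 and 1. Why these numbers differ was not tested: more calls came with more genes tested as well as with fewer.

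Leaving out 1 library gave 0 to 4 genes higher and 0 to 2 lower, with fewer samples in each fit. The 0 higher calls without Control replicate 3 and without OcKO replicate 3 stood beside 1614 and 941 genes higher at an unadjusted p under 0.05. In every such fit the 22 genes kept a positive fold change. This was all but fixed in advance, since all their OcKO libraries lay above all Control libraries. The Rpa1 log2 fold change lay between -4.78 and -4.33, and its adjusted p passed 0.05 in 3 of the 6. Of the 580 values of other genes picked for naming under alternatives, 459 stayed on their side of the threshold, 3 of them uncalled with the other sign, 91 lost the call and 30 gained one.

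The replicate numbers did not pair the samples: the correlations of same-numbered deviations were -0.0370, -0.0448 and -0.0450, and no sample correlated best with its own number. With a replicate block, edgeR called 0 genes higher and 0 lower (813 and 563 at an unadjusted p under 0.05), the Rpa1 log2 fold change was -4.63 (adjusted p = 0.159), and 6 lists passed camera.

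For the lists, 7 passed camera with the preset correlation, 0 with an estimated correlation, 6 with library size alone and 4 to 8 without 1 library. With fry, which does not compare a list with other genes, 4 passed. They were the p53, mitochondrial, apoptosis and RPA lists, the last through Rpa1 itself. Of 290 list values, 265 stayed on their side of the threshold, 17 of them uncalled with the other direction, 21 lost the call and 4 gained one. The p53, mitochondrial, oocyte growth and mRNA storage lists passed camera in all 6 fits without 1 library. The span difference was -0.39 for genes with a name other than Gm or Rik (exact permutation p = 0.1), -0.16 for the longest and shortest 10%, -0.08 after regression on exonic length and mean expression, and -0.29 to -0.09 without 1 library. Within 10 Mb of Rpa1, 0 of 281 genes were called, a share below that elsewhere (Fisher's exact p = 1), and within 40 Mb 2 of 842, a share above it, as at 20 Mb (p = 0.322). Without 1 library, 0 were called within 20 Mb in each of the 6 fits. All 56 library composition values stayed within 1 SD, pooled as the root of the mean of the variances of both groups. Most of these values leave out 1 library. With 3 libraries per group that cannot move the difference by 1 such SD, so their outcome was fixed in advance. The spread between replicate libraries, which edgeR gives as a biological coefficient of variation of 0.746, limits calls of small changes: 4.35% of simulated 2-fold changes were called.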

Other observations

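Thinning of the libraries, the median and highest gain of granulosa markers, the count of markers with a gain and the bootstrap interval were chosen after seeing the data; the other tests were fixed before their results were seen. More genes than those called were near absent in Control and present in every OcKO library. With at most 3 counts over the Control libraries and at least 1 CPM in every OcKO library, there were 79 such genes, 72 of them protein coding, and the reverse was met by 1 gene. Of the 79, 11 were called by edgeR over all genes. Those with the highest OcKO level that were not called, named after their values were seen, were Ovol2, an epithelial transcription factor (2 Control counts, mean 34.7 CPM scaled to library totals in OcKO; edgeR adjusted p = 0.0675), and Plch2, a phospholipase C gene (2 Control counts, 24.2 CPM; adjusted p = 0.0590).

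Several technical sources were tested for these 79 genes. With all libraries thinned to the smallest total, 81 genes met the definition against 1 of the reverse kind, a ratio of 81, which argues against deeper OcKO libraries. Genomic DNA would raise olfactory and vomeronasal receptor genes, whose summed CPM was 1.07 times that of Control. The sums were 600 ± 84.0 CPM in Control and 644 ± 177 CPM in OcKO (SD, n = 3). With that base and spread, a small share of genomic DNA would not be seen. Ovarian somatic or blood cells cannot be told apart from a change in the oocyte. The median gain over the 72 markers of other cell types was 0.031 CPM against 4.53 CPM for the 79 genes, or 0.686%. The markers belong to several cell types, so cells of a single type would leave that median near 0, and 10 of the 72 gained more than 4.53 CPM. Nr5a1 is both a granulosa marker and 1 of the 79 genes, and the tested theca, stroma and endothelial markers had a median log2 fold change of 0.74. A different set of surviving oocytes in the OcKO ovary also stays open, and no test here tells these apart.

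For the 22 genes higher in OcKO, cumulus or granulosa cells are argued against by a ratio of summed granulosa marker CPM of 0.942. Since Bmpr1b and Esr2 hold most of that sum, the median gain over 27 markers was also taken: 0.222 CPM against 39.8 CPM for the 22 genes, or 0.557%, and the highest gain of any of the 27 was 16.5 CPM. Of the 10 splits of the 6 samples into 3 and 3, only the real split, 1 of 10, called as many genes (23), and the highest of the others called 0. For lists the real split called 7, again 1 of 10, and the highest of the others 3. With 10 splits no share under 0.05 can be reached.

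The mitochondrially encoded transcripts had a positive median log2 fold change under each of 3 scalings, the lowest 1.09. By edgeR, 0 of the 13 were called over all genes, and camera with an estimated correlation gave an adjusted p of 0.115. DESeq2 size factors and library size alone moved the median of all tested genes up, by 0.02 and 0.17. They could thus not lower the list, and the choice among the 3 scalings does not account for its rise. All 3 are relative to the counts of the same library, so the amount of these transcripts per oocyte was not addressed. Whether other cells carry more of these transcripts than oocytes was not measured here. If they do, a share of them would raise the list, and the 36 detected markers of other cell types had a median log2 fold change of -0.00601 with a bootstrap interval of -0.53 to 0.65. The markers went both ways and their interval reaches within 0.5 of the mitochondrial median, so a small share of other cells cannot be told apart from a change in the oocyte. A share of mitochondrial transcripts of 0.0665% to 0.187% is low in all 6 libraries, and how the counting treated reads with nuclear copies is not known.

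The lower oocyte growth and mRNA storage lists may reflect a general fall of abundant transcripts. The median log2 fold change of their 87 genes was -0.26, at percentile 4.93 of 10000 random lists matched on mean expression, whose median was -0.17 and whose 2.5th percentile was -0.27. The value lies between the bounds set in advance, so the lists and abundant transcripts in general cannot be told apart.

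A loss of transcripts with genomic span was the hypothesis behind the test of long genes. After regression on exonic length and mean expression, Spearman's rho across genes was -0.0695, between the bounds set in advance, and over all tested genes the OcKO libraries overlapped the Control libraries. For genes with a name other than Gm or Rik they did not overlap (difference -0.385, exact permutation p = 0.1, the smallest this design allows), so it stays open. Strain sequence flanking the targeted allele stays open as well (Fisher's exact p = 0.139, 2 called genes within 20 Mb), with 0 called genes within 10 Mb and 0 within 20 Mb in each of the 6 fits without 1 library, which called 0 to 4 genes higher.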
